A study of Mus musculus with 32 samples.

How the data were processed

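Whole blood of 32 mice was collected per the labels by cardiac puncture into PAXgene tubes 24 h after exposure to X-rays or sham treatment. RNA was extracted, depleted of globin transcripts, labelled with Cy3 and hybridised to Agilent 1-colour mouse arrays, 1 array per mouse. Samples were grouped by the genotype and dose in the labels into 6 groups (WT 0 and 8 Gy, Atm 0 and 4 Gy, Scid 0 and 3 Gy), and no sample was moved between groups on the basis of its values.

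The authors deposited 1 scanner table per array, whose processed signal is an intensity for each spot, background-subtracted and detrended within the array by Agilent Feature Extraction and not normalized between arrays. The version is 12.0.2 per the labels and 11.5.1.1 per the file headers. The deposited series matrix holds log2 values of the same arrays for 15276 to 20163 probes per array. Between 98.12 and 99.12% of them lay within 0.01 of the log2 processed signal plus a constant for the array, so their scale and direction are known, while how the constant and the probes with a value were chosen is not. The column medians ran from 5.51 to 6.44, and 10413 probes had a value on all arrays. The series matrix was used as an alternative.

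Control spots and spots marked as non-uniform outliers (125 to 324 per array) were left out, spots of the same probe (399 probes with replicate spots) were averaged, and saturated spots (at most 3 per array) were kept. The log2 processed signal of each array was set to its own 75th percentile. A probe was kept if it was well above background on at least 4 arrays of at least 1 group, which 18367 of 39429 probes were. Probes were named through their accession in the reference table (27508 probes), or else by symbol (3544) or synonym (404), and 7973 kept the name in the file, with 2421 symbols updated. Each gene was represented by its kept probe of highest mean signal, giving 15159 genes, of which 12210 carried a reference symbol, with 275 missing values among them. Among called genes with another kept probe, the other probe had the opposite sign for 36 of 279 probes in WT (2 of them at an unadjusted p under 0.05), 1 of 12 in Atm (1) and 5 of 43 in Scid (0). Positions are those of the probes in build mm9, named in the file headers. The reference table is of another assembly, and none of its positions were used.

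Signal over background took the place of depth, at 20.02 to 58.6% of probes well above background per array and a 75th percentile of the signal from 17.1 to 232.0. A gene whose probes were not well above background on any array of a group has only a bound there, given as "at least N-fold" between the bright group's mean and the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own.

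The 6 group means were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 on all 32 arrays, so that all groups share 1 estimate of spread per gene. The comparisons were irradiated against 0 Gy within each genotype, Atm against WT and Scid against WT at 0 Gy, and the 3 pairwise differences between the irradiation responses. The 2 interactions with WT share the 11 WT arrays and both 0 Gy comparisons share the WT controls, so no overlap between these was counted. P-values were two-sided and adjusted by Benjamini and Hochberg over the 15159 genes of each comparison, and a gene was called at an adjusted p under 0.05. Overlaps between genotypes were tested with the hypergeometric distribution over the genes tested. The 23 gene lists of pathways and cell types were tested with camera at a preset inter-gene correlation of 0.01, and beside it with an estimated correlation, with fry, and with an exact permutation test of each list's score (the mean of its members less the mean of all genes on the array, two-sided), each adjusted over the 23 lists. Members of a list were also adjusted over the list alone. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 read the files and drew the figures.

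The groups, comparisons, lists, thresholds, most alternatives and the rule for named genes were fixed before the data were examined. The rule takes, in each irradiation comparison, the 10 genes with the largest rise and the 10 with the largest fall among called genes with a symbol whose groups do not overlap. It takes likewise 8 and 8 in each 0 Gy comparison and the 5 and 5 largest called interactions. Of each called list it takes up to 3 called members of largest change, or the 2 brightest members where none was called, and 18 genes were always looked up. The text names fewer than the rule gives, and other genes it names are marked as chosen after their values were seen. Results of some genes of the rule are not reported here.

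Alternatives recomputed with 1 choice changed at a time were normexp background correction (offset 50), quantile normalization, scaling to the array median, no filter on dim probes, only probes well above background on all arrays, slide as a random or fixed block, slide series, scan day and replicate number as fixed blocks, only the 2 groups compared, eBayes with trend and robust settings, array weights, the mean of all kept probes of a gene, the series matrix values, and each array left out in turn. Scaling to the 75th percentile of probes detected on all arrays, scaling to 7 spike-in probes, genes detected in a group compared, leaving out 3 dim arrays (under 30% of probes well above background), 2 arrays with unlike lymphocyte scores or 4 arrays bright in liver genes, brightness as a covariate and the exact permutation test of list scores were added after seeing the data.

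The pipeline was tested on simulated data with the same group sizes, in which 50 genes were changed by each fold. In WT 0, 14, 68 and 86% of genes changed by 1.5-, 2-, 4- and 8-fold were recovered with 2 false calls, in Atm 0, 8, 62 and 90% with 2, and in Scid 0, 8, 52 and 86% with 4. In the 0 Gy comparison of Atm with WT 0, 8, 66 and 88% were recovered with 1 false call and in that of Scid with WT 0, 8, 68 and 86% with 4. For the interactions recovery was 0, 0, 32 and 72% with 1 false call (Atm minus WT), 0, 2, 30 and 44% with 4 (Scid minus WT) and 2, 8, 34 and 76% with 2 (Scid minus Atm). A list shifted by -1 on the log2 scale was called in all 8 comparisons, with 0 of the other 22 lists called in 7 of them and 1 in Scid minus Atm. The simulated genes were drawn independently of each other. These list counts therefore say nothing of false list calls where genes of a list are correlated, as in real arrays. The simulation also held no slides, scan days, dim arrays or arrays bright in liver genes. Its false gene calls are thus not an error rate for the real arrays. Of 100 splits of the real arrays of Scid and WT at 0 Gy, 94 called no gene, but the highest called 1154.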

Results

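Gene expression was measured in whole blood of 32 mice on Agilent 1-colour arrays, 24 h after whole-body X-irradiation or sham treatment (0 Gy). The mice were wild type (WT), deficient in the DNA damage kinase ATM (Atm), or Scid, a strain whose mutation in Prkdc impairs DNA end joining. The groups were WT at 0 Gy (n = 6) and 8 Gy (n = 5), Atm at 0 Gy (n = 5) and 4 Gy (n = 6), and Scid at 0 Gy (n = 5) and 3 Gy (n = 5). Each genotype received the dose that the labels describe as equally lethal for it, so genotype and dose change together and no comparison of the responses can separate them. Signal over background took the place of depth. The share of probes well above background per array was 28.0 to 53.3% in WT at 0 Gy and 45.8 to 58.6% at 8 Gy. In Atm it was 36.6 to 43.4% at 0 Gy and 20.02 to 48.1% at 4 Gy, and in Scid 25.0 to 47.7% at 0 Gy and 32.5 to 43.2% at 3 Gy. The irradiated WT arrays were brighter than their controls, and the number of arrays per group limits the precision. The arrays lay on 9 slides scanned on 4 days (15, 12, 4 and 1 arrays). Of 39429 probes, 18367 passed the detection filter, and 15159 genes were tested.

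The probes of Atm (2 probes) and Prkdc (1 probe) did not pass the detection filter in any group, so the targeted genes give no check of the genotype labels. Positions below are probe positions in mouse build mm9, which the file headers name. Levels are log2 signal with each array's 75th percentile at 0, and changes are log2 fold changes with their standard error (SE) from limma.

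In WT mice the comparison of 8 Gy with 0 Gy asks how blood transcripts respond to the dose in normal animals. Genes of the p53 pathway rose: 14 of 39 listed p53 targets rose and 2 fell. Cdkn1a, the cyclin-dependent kinase inhibitor p21, rose by 3.86 (SE 0.51, adjusted p = 4.53e-06, chromosome 17, 29237377 to 29237436), from -1.62 ± 0.54 (SD, n = 6, well above background on 3 arrays) at 0 Gy to 2.24 ± 0.62 (SD, n = 5, on 5 arrays). Its other kept probe rose by 1.86. The stress cytokine gene Gdf15 rose by 3.49 (SE 0.91) and the thiamine transporter gene Slc19a2 by 2.54 (SE 0.63). Phlda3, a repressor of AKT signalling, rose by 2.28 (SE 0.56), Ccng1, which encodes cyclin G1, by 2.10 (SE 0.58) and the pro-apoptotic gene Bax by 1.58 (SE 0.36). Mdm2, the p53 ubiquitin ligase, was 1.07 higher (SE 0.37, adjusted p = 0.0748) and did not pass the test. The 2 members that fell, chosen here after their values were seen, were Ptpn14 (-2.27) and Abhd4 (-1.40), whose call was lost in 8 of the 11 omissions of 1 array (-1.24 at the weakest). The list's median was 1.07 (adjusted p = 7.68e-11 with the preset correlation, adjusted p = 0.0348 with an estimated correlation), with all 5 irradiated arrays above every control in its score.

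Erythroid transcripts fell in irradiated WT mice. Of 37 erythroid and reticulocyte genes, 26 fell and none rose, with a median of -2.89. The red cell membrane genes Slc4a1 (band 3, -4.88, SE 0.61) and Epb42 (protein 4.2, -4.85, SE 0.47, adjusted p = 8.35e-08, chromosome 2, 120844440 to 120844499) fell, with all 5 irradiated arrays below every control. Ank1, the red cell ankyrin gene, was at least 36.6-fold lower (adjusted p = 8.48e-07), since it was not well above background on any array at 8 Gy. Alas2, the erythroid haem synthesis gene, fell by 1.48 (SE 0.38) from 12.51 ± 0.95 (SD, n = 6). The list's shift passed the preset test (adjusted p = 3.23e-28) and the exact permutation test of its score (p = 0.00433, adjusted p = 0.0249), but had adjusted p = 0.0795 with an estimated correlation.

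Cell cycle transcripts fell as well: 11 of 30 proliferation genes fell and none rose. Among them were Nusap1, a spindle protein gene (-4.02, SE 0.45), Ccna2, which encodes cyclin A2 (-3.84, SE 0.43), and the proliferation marker Mki67 (-2.55, SE 0.46). The list's median was -0.45 and its mean -1.06 (preset adjusted p = 1.64e-06, adjusted p = 0.282 with an estimated correlation, exact permutation p = 0.00433), and its median was 0.82 when the arrays were scaled to spike-in probes.

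Interferon-stimulated genes rose: 11 of 36 rose and 3 fell, with a median of 1.11, which became -0.57 when tested on the few members detected on all arrays. The antiviral genes Oas2 (4.07, SE 0.80), Ifit3 (3.46, SE 0.78) and Mx1 (3.12, SE 0.61) rose, as did Slfn4, a Schlafen family gene of myeloid cells, by 4.21 (SE 0.73, adjusted p = 0.000174). The members that fell were Rsad2, the viperin gene (-3.84, SE 0.54), and, chosen after their values were seen, Isg15 (-2.33) and Oas3 (-2.62). All 5 irradiated arrays had a higher list score than any control (preset adjusted p = 6.92e-08, exact permutation p = 0.00216, the smallest possible, adjusted p = 0.0248). The call was lost with an estimated correlation (adjusted p = 0.481).

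Blood cell markers moved in both directions in WT. Of 29 monocyte markers 2 rose, Ms4a6d (2.38, SE 0.58) and the endotoxin co-receptor gene Cd14 (2.07, SE 0.53). Ms4a4c fell (-1.16, SE 0.36, but 0.13 with normexp background correction and 0.12 with spike-in scaling, and -0.03 and -0.51 on its other probes). The list's median was 0.63 (adjusted p = 0.00743, adjusted p = 0.627 with an estimated correlation). The call was also lost with the detected-probe percentile, with spike-in scaling and with brightness as a covariate (adjusted p up to 0.171). The scavenger receptor gene Marco rose by 3.93 (SE 1.03) and the acute phase gene Saa3 by 4.14 (SE 1.31, adjusted p = 0.0478). Liver transcripts were bright on 4 arrays (WT 0 Gy replicate 5, WT 8 Gy replicates 1 and 2 and Atm 4 Gy replicate 3). Without these, Saa3 (4.304) and Marco (4.06) no longer passed, although neither rise was smaller and fewer arrays were left. In WT 754 genes then passed. Of 24 B cell markers 4 fell. They were Vpreb3 (-4.35, SE 0.56), the B lineage factor gene Ebf1 (-2.42, SE 0.62), the complement receptor gene Cr2 (-2.35, SE 0.61) and, chosen after its value was seen, Fcer2a (-2.23). The B cell antigen receptor gene Cd79a (-1.24, adjusted p = 0.327, -1.85 to -0.76 when 1 array was left out) did not pass. The B cell list's median was -0.91 (adjusted p = 0.00108, adjusted p = 0.491 with an estimated correlation, exact permutation p = 0.219) and was 0.37 with spike-in scaling.

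Globin, ribosomal protein and platelet lists were also called in WT. The globin list had a median of -1.26 (adjusted p = 0.000168, adjusted p = 0.481 with an estimated correlation), with Hbq1a (-1.77, SE 0.50) and the embryonic gene Hbb-y (-1.64, SE 0.42) passing of 8 members. The labels state that globin transcripts had been depleted from the RNA. The globin median was 0.13 with normexp and 0.13 with spike-in scaling. The ribosomal protein list had a median of -0.61 (adjusted p = 2.16e-05, adjusted p = 0.491 with an estimated correlation) but of 0.67 with normexp, 0.07 with quantile normalization and 0.67 with spike-in scaling. Of its 34 members 5 fell, among them Rps14 (-1.35, SE 0.32, but 0.01 with normexp) and Rplp2 (-1.22, SE 0.37, but 0.06 with normexp and with spike-in scaling). The platelet list had a median of 0.31 with no member passing (adjusted p = 0.0264, adjusted p = 0.77 with an estimated correlation), a call lost with slide as a block.

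Of the 15159 genes, 1092 passed at adjusted p under 0.05 in WT, 172 higher and 920 lower, and 3144 had an unadjusted p under 0.05. In 84 of the higher and 480 of the lower genes the groups did not overlap. Over all genes 5.07% did not, against 0.433% by chance. With slide as a fixed block 539 genes passed (521 of the 1092 among them) and with scan day 820 (789 of the 1092). Within the first day (1 irradiated array and 3 controls) and the second (3 and 2) the list scores differed by 1.49 and 0.98 for p53 targets, -2.75 and -2.00 for erythroid genes, -1.05 and -0.79 for proliferation genes and 1.44 and 0.82 for interferon-stimulated genes. They differed by 1.098 and 0.48 for monocyte markers, -0.72 and -1.72 for B cell markers, -1.79 and -0.76 for globin genes, by -0.16 and -0.66 for ribosomal protein genes, and 0.17 and 0.74 for the platelet list. On the slides that held both groups, with 1 array of each, the platelet score differed by -0.56 and -0.77, against the called direction. On the one that held WT 0 Gy replicate 3 the B cell score differed by 1.61 and that of ribosomal protein genes by 0.13. With scan day and with slide as a block the list medians were, in the same order, 1.05 and 1.06, -2.74 and -2.94, -0.44 and -0.77, and 1.17 and 1.32. For the remaining lists they were 0.64 and 0.40, -1.20 and -0.92, -1.35 and -1.33, -0.65 and -0.68, and 0.30 and 0.11. The balance between higher and lower genes depended on the processing and on single arrays. It was 357 against 234 with normexp, 39 against 500 with slide as a block, 1139 against 1920 with array weights, 60 against 694 without the liver-bright arrays, 426 against 601 with the authors' normalized values, 787 against 619 with the percentile of the probes detected on all arrays and 4050 against 163 with spike-in scaling. Leaving out WT 8 Gy replicate 1 gave 688 genes (68 higher), WT 8 Gy replicate 4 842 (71 higher) and WT 0 Gy replicate 5 1835 (356 higher). The call of Marco was lost without WT 8 Gy replicate 1 or 4 (3.38 at the lowest) and that of Gdf15 without WT 8 Gy replicate 4 (2.99). Without WT 8 Gy replicate 1 those of Cr2 (-2.14), Fcer2a (-1.88) and the monocyte list (median 0.41) were lost. Ccng1 was lost without WT 0 Gy replicate 4 or WT 8 Gy replicate 4 (1.96 at the lowest), and Alas2 and Hbb-y without WT 8 Gy replicate 1 or 2 (-1.31 and -1.38 at the weakest). The call of the platelet list was lost without any 1 of WT 0 Gy replicates 1, 2 and 5 and WT 8 Gy replicates 3, 4 and 5 (0.03 at the lowest). Saa3 passed only with all arrays or without WT 0 Gy replicate 2 or 5 (3.71 to 4.56 over the 11 omissions), and Ms4a4c only with all or without WT 0 Gy replicate 1 or 2 or WT 8 Gy replicate 2 (-1.30 to -1.02). Rplp2 (-1.52 to -0.995) and Hbq1a (-2.11 to -1.41) lost their calls without any 1 of WT 0 Gy replicates 1, 3, 4 and 6 and WT 8 Gy replicates 1 and 2, and Rplp2 also without WT 8 Gy replicate 4.

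**Figure D1:**
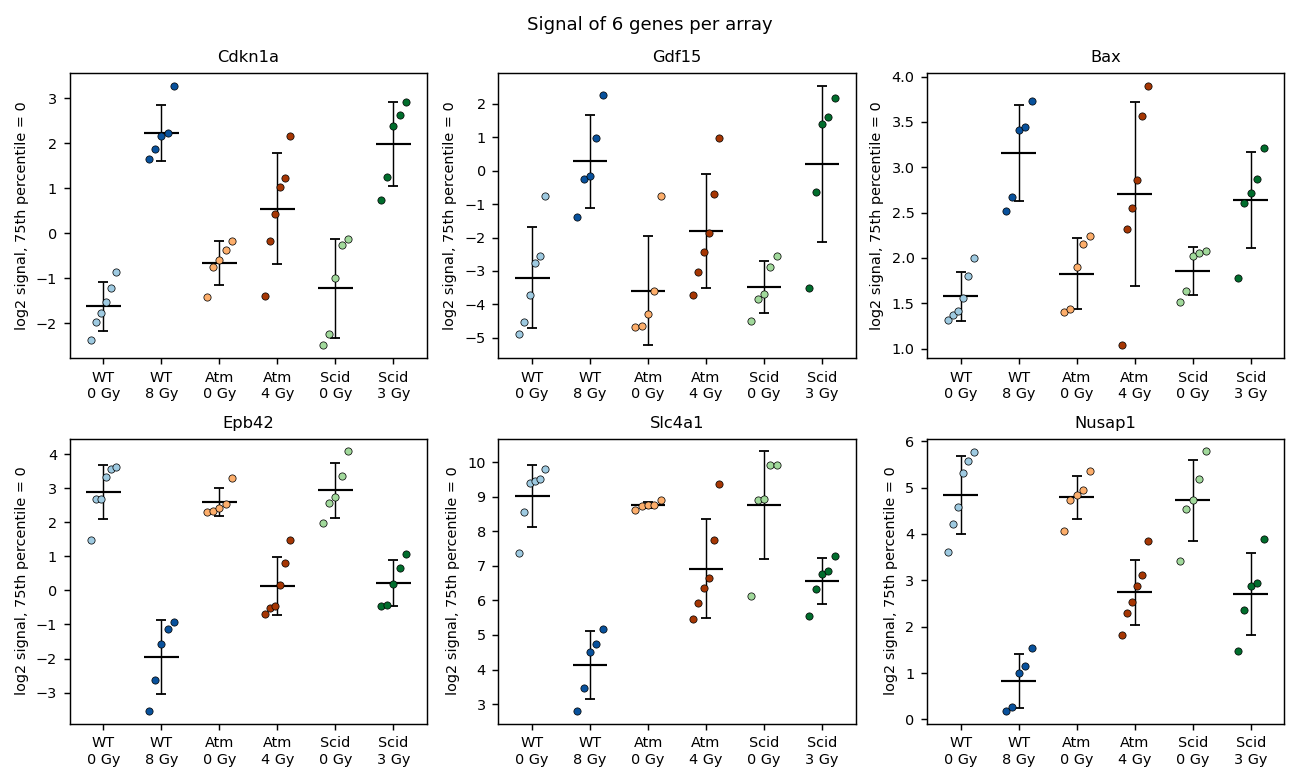
Log2 signal (array 75th percentile at 0) of Cdkn1a, Gdf15, Bax, Epb42, Slc4a1 and Nusap1 in each of the 32 arrays by group, with lines at the group mean and bars of 1 SD. Cdkn1a at 8 Gy in WT (mean 2.24) and at 3 Gy in Scid (mean 1.99) lies above every control of its genotype.

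In Atm mice the comparison of 4 Gy with 0 Gy asks the same in the absence of ATM. All 24 B cell markers had a lower mean, with a median of -1.56 (preset adjusted p = 8.83e-10), a call lost with an estimated correlation (adjusted p = 0.46) and in the exact permutation test (p = 0.00649, adjusted p = 0.0995). Of them Vpreb3 fell by 2.57 on the log2 scale (SE 0.56, adjusted p = 0.0425). Adjusted over the list alone, 12 of the 24 fell. Ccr6, a chemokine receptor gene of B and T cells, had -2.48 (SE 0.56, adjusted p = 0.0453), Cd79a -2.34 (SE 0.70, adjusted p = 0.111) and the MHC class II gene H2-Ab1 -1.66 (SE 0.81, adjusted p = 0.409), the latter pair not passing. The erythroid gene Epb42 fell (-2.45, SE 0.47, adjusted p = 0.0218), as did Nusap1 (-2.05, SE 0.45, adjusted p = 0.0425). Hydin, a gene of the axoneme of motile cilia, rose by 3.12 (SE 0.59, adjusted p = 0.0196) from -2.52 ± 1.27 (SD, n = 5, well above background on 2 arrays), and the NADPH oxidase gene Nox1 rose by 3.09 (SE 0.70, adjusted p = 0.0453) from -3.23 ± 1.13 (SD, n = 5, on 1 array).

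None of the 39 p53 targets passed in Atm: Cdkn1a was 1.21 higher (SE 0.51, adjusted p = 0.316), above every control in 4 of 6 arrays, and Bax 0.88 higher (SE 0.36, adjusted p = 0.3). As a group p53 targets were higher (median 0.41, adjusted p = 0.000216, adjusted p = 0.46 with an estimated correlation; -1.09 with spike-in scaling). B cell markers were also called with fry (adjusted p = 0.0198). Called with the preset correlation were MHC class II genes (all 10 members lower, median -1.44, adjusted p = 0.000843, adjusted p = 0.583 with an estimated correlation) and erythroid genes (28 of 37 lower, median -1.17, adjusted p = 8.83e-10, adjusted p = 0.573 with an estimated correlation). Proliferation genes (23 of 30 lower, median -0.59, adjusted p = 0.00523, adjusted p = 0.696 with an estimated correlation) and ribosomal protein genes (30 of 34 lower, median -0.38, adjusted p = 0.00516, adjusted p = 0.99 with an estimated correlation) were called lower. The platelet list was called higher (median 0.06, adjusted p = 0.0462, adjusted p = 0.99 with an estimated correlation), with a median of -0.13 with the array median, -0.08 with the authors' values and -1.44 with spike-in scaling. Interferon-stimulated genes had a median of 0.08 and were not called, but the arrays differed. Atm 4 Gy replicates 1 and 4 had list scores of 1.897 and 1.503, above every WT 8 Gy array (1.38 at the highest), and the others lay between -0.66 and 0.08.

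With limma, 36 genes passed in Atm, 11 higher and 25 lower, and 1829 had an unadjusted p under 0.05. Over all genes 2.13% did not overlap between the groups, against 0.433% by chance. With scan day or slide as a fixed block no gene passed (0 and 0). The 36 kept their direction with scan day as a block, but their median size fell from 2.05 (median SE 0.41) to 1.55 (median SE 0.42), which ended the calls. Only the first and the third day held both groups, with 4 and 1 controls against 1 and 1 irradiated arrays. Within them the list scores differed by -1.86 and -1.32 for B cell markers, -1.58 and -1.77 for MHC class II genes and 0.95 and -0.09 for p53 targets. They differed by -0.15 and -0.15 for erythroid genes, -0.16 and -0.42 for proliferation genes, 0.13 and -0.38 for ribosomal protein genes and 1.24 and -0.83 for the platelet list. With scan day and with slide as a block their medians were, in the same order, -1.62 and -1.65, -1.44 and -1.41, 0.54 and 0.55, -0.61 and -0.57, -0.24 and -0.24, -0.29 and -0.29, and 0.39 and 0.44. The proliferation call was lost with either block. The number of genes depended on single arrays. It was 2 without Atm 0 Gy replicate 2, 4 without Atm 4 Gy replicate 4, 5 without Atm 4 Gy replicate 5, and 6 without Atm 0 Gy replicate 4 or Atm 4 Gy replicate 3. It was 18 without Atm 0 Gy replicate 5, 19 without Atm 0 Gy replicate 3, 71 without Atm 4 Gy replicate 6 and 274 without Atm 4 Gy replicate 1. All 6 named genes that passed lost their call without Atm 0 Gy replicate 2 or 4 or Atm 4 Gy replicate 4 or 5, and those other than Hydin also without Atm 0 Gy replicate 3 or Atm 4 Gy replicate 3. Over the 11 omissions Hydin lay between 2.69 and 3.45, Nox1 between 2.76 and 3.395 and Vpreb3 between -2.82 and -2.41. Ccr6 lay between -2.70 and -2.18, Epb42 between -2.72 and -2.27 and Nusap1 between -2.27 and -1.86. Nox1, Vpreb3 and Ccr6 were also lost without Atm 0 Gy replicate 5, Nox1 without Atm 4 Gy replicate 6, Vpreb3 without Atm 4 Gy replicate 2, and Vpreb3, Ccr6 and Nusap1 without Atm 0 Gy replicate 1. The platelet call was lost without Atm 0 Gy replicate 1, 4 or 5 or Atm 4 Gy replicate 1 or 4 (medians -0.20 to 0.39 over all omissions). Higher and lower genes numbered 73 and 35 with the percentile of probes detected on all arrays and 14 and 170 with the array median. They numbered 36 and 303 with the authors' values, and 7 and 10775 with spike-in scaling.

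In Scid mice the comparison of 3 Gy with 0 Gy asks the same where end joining is impaired. The p53 targets Cdkn1a, Aen and Gdf15 rose, 3 of 39. Cdkn1a rose by 3.22 (SE 0.54, adjusted p = 0.00304), from -1.23 ± 1.101 (SD, n = 5, well above background on 3 arrays) to 1.99 ± 0.94 (SD, n = 5). Its other kept probe rose by 1.11. The apoptosis-enhancing nuclease gene Aen rose by 2.05 (SE 0.48, adjusted p = 0.0262), and Gdf15 was at least 3.64-fold higher (adjusted p = 0.0479; well above background on 4 of 5 irradiated and 0 of 5 control arrays). Phlda3 was 1.86 higher (SE 0.59, adjusted p = 0.137). Of 37 erythroid genes 9 fell, among them Epb42 (-2.73, SE 0.50) and the carbonic anhydrase gene Car2 (-2.61, SE 0.51). Of 30 proliferation genes Nusap1 fell (-2.02, SE 0.47). Outside these lists Rbbp4, a histone-binding protein gene, fell (-2.48, SE 0.44). P2ry10, a lymphocyte receptor gene, was at least 2.92-fold lower (adjusted p = 0.0137, well above background on 3 of 5 controls).

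As groups in Scid, erythroid genes had a median of -1.15 (adjusted p = 3.34e-12, adjusted p = 0.508 with an estimated correlation, exact permutation p = 0.00794, adjusted p = 0.146). Proliferation genes had -0.78 (26 of 30 lower, adjusted p = 4.87e-07, adjusted p = 0.444 with an estimated correlation) and ribosomal protein genes -0.58 (33 of 34 lower, adjusted p = 8.14e-08, adjusted p = 0.588 with an estimated correlation). NK cell markers had -0.64 (21 of 23 lower, adjusted p = 0.000385, adjusted p = 0.719 with an estimated correlation). On the higher side were p53 targets with 0.37 (28 of 39 higher, adjusted p = 0.000112, adjusted p = 0.444 with an estimated correlation) and the platelet list 0.62 (28 of 29 higher, none passing singly, adjusted p = 7.04e-06, adjusted p = 0.72 with an estimated correlation). Interferon-stimulated genes had a median of 0.15 (adjusted p = 0.693).

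In all, 163 genes passed in Scid, 9 higher and 154 lower, and 1452 had an unadjusted p under 0.05. Of all genes 2.69% did not overlap, against 0.794% by chance. With slide as a fixed block 85 genes passed (78 of the 163 among them) and with scan day 69 (68 of the 163). Within the first and the second day the list scores differed by -0.81 and -0.75 for erythroid genes, -0.79 and -0.16 for proliferation genes and -0.36 and -0.98 for ribosomal protein genes. They differed by -0.72 and -0.76 for NK markers, 0.41 and 0.84 for p53 targets and 0.83 and 0.90 for the platelet list. With scan day and with slide as a block their medians were -0.96 and -1.25, -0.67 and -0.64, -0.48 and -0.48, -0.46 and -0.32, 0.34 and 0.53, and 0.77 and 0.60. The NK call was lost with slide as a block. With normexp and with spike-in scaling 0 genes passed. Leaving out 1 array gave 43 genes (Scid 0 Gy replicate 2), 45 (Scid 3 Gy replicate 3), 60 (Scid 0 Gy replicate 1), 71 (Scid 3 Gy replicate 4), 85 (Scid 3 Gy replicate 5), 106 (Scid 0 Gy replicate 3) or 403 (Scid 0 Gy replicate 5). Cdkn1a, Epb42, Car2 and Rbbp4 passed in each of the 10 omissions. Nusap1 did not without Scid 0 Gy replicate 1 or 2 or Scid 3 Gy replicate 3 or 4 (-1.71 at the weakest), nor Aen without these 4 or Scid 3 Gy replicate 5 (1.57), nor P2ry10 without Scid 3 Gy replicate 3. Gdf15 passed only with all arrays or without Scid 0 Gy replicate 5 or Scid 3 Gy replicate 2.

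**Figure D2:**
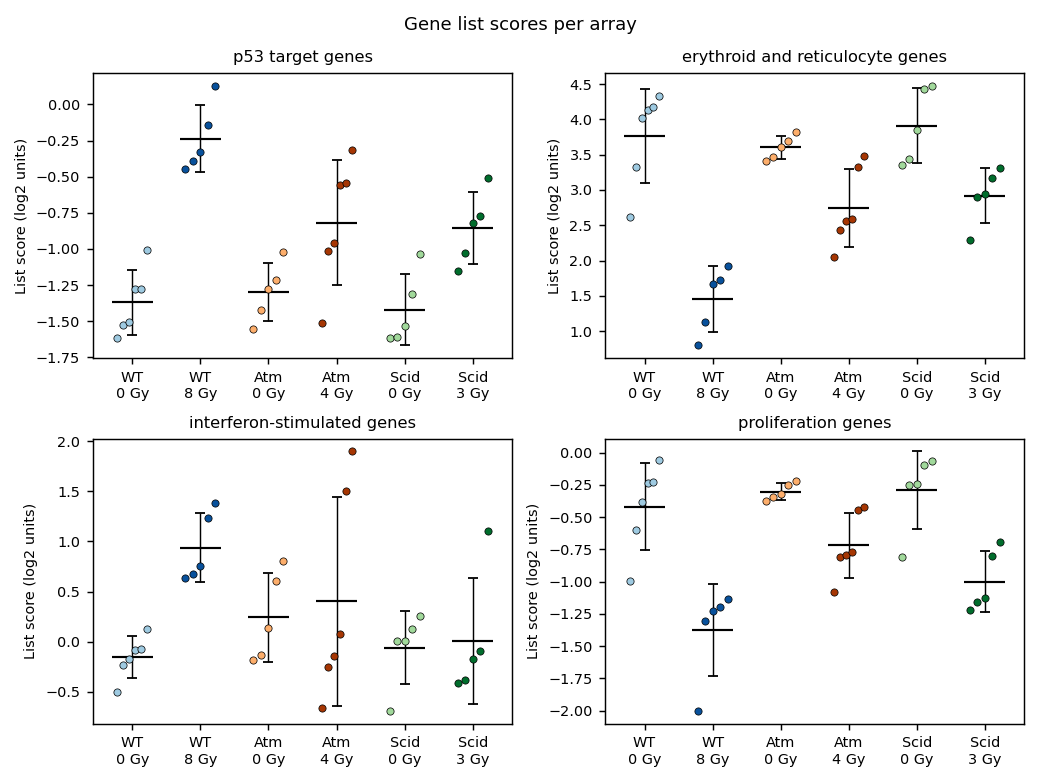
Mean log2 signal of the p53 target, erythroid, interferon-stimulated and proliferation lists, less the mean of all genes, in each of the 32 arrays by group, with lines at the group mean and bars of 1 SD. In WT the 5 arrays at 8 Gy lie apart from the 6 controls in all 4 panels.

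Many of the genes that fell were shared between genotypes, where the 3 comparisons have no arrays in common but use 1 spread per gene estimated from all arrays. Of the lower genes, 133 were shared by WT and Scid (9.35 expected, exact hypergeometric p = 1.48e-141), 20 by WT and Atm (1.52 expected, p = 1.5e-20) and 14 by Atm and Scid (0.25 expected, p = 2.77e-22). Genes are not independent of each other, which these p-values do not allow for. The 14 were lower in all genotypes and included Epb42 and Nusap1. With scan day or slide as a fixed block 0 genes passed in Atm, so no gene, lower or higher, then stayed shared with Atm. Of the higher genes, Cdkn1a, Aen, Gdf15 and Kank3 (4) were shared by WT and Scid (0.1 expected, exact hypergeometric p = 1.93e-06). Gm14308 and Tmem170b (2) were shared by WT and Atm (0.12 expected, exact hypergeometric p = 0.00658), and 0 by Atm and Scid (0.01 expected). Kank3, Gm14308 and Tmem170b were chosen after their values were seen, and Kank3 lost its call in Scid in 5 of the 10 omissions. The other kept probe of Kank3 rose by 1 in WT and 0.75 in Scid, against 1.91 and 1.55 on the probe used. The 145 genes shared by at least 2 genotypes became 0 with normexp, 62 with scan day as a block, 79 with slide as a block and between 52 and 319 when 1 array was left out. With each genotype fitted on its own 2 groups, where fewer arrays estimate the spread, there were 30, and none in Atm, where 0 genes passed. Across all genes the log2 fold changes of WT and Atm had r = 0.437, those of WT and Scid r = 0.391 and those of Atm and Scid r = 0.374.

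**Figure D3:**
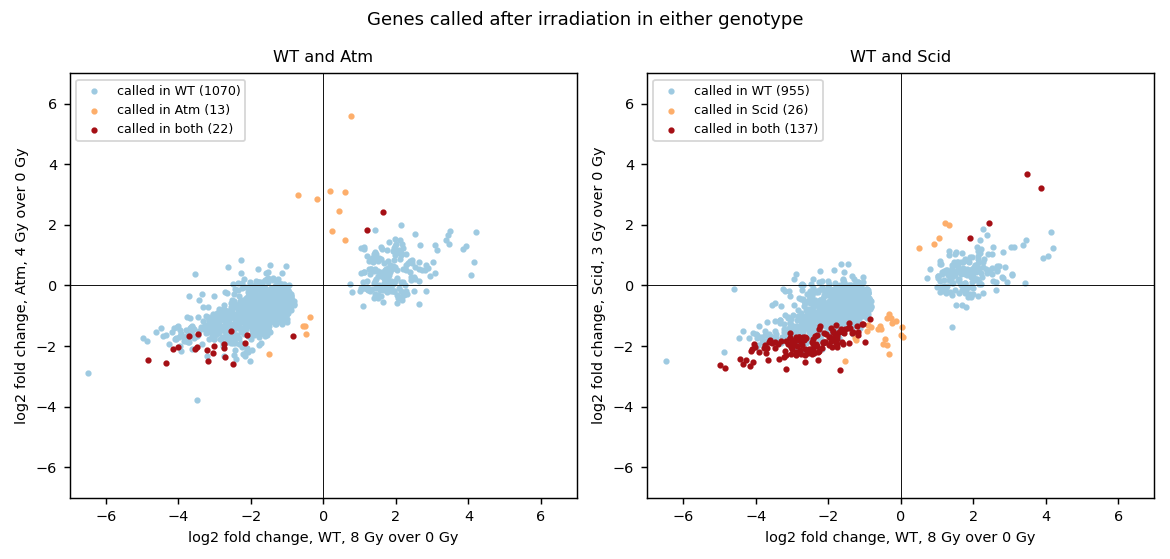
Log2 fold change on irradiation in WT (horizontal) against Atm and against Scid (vertical) of the genes that passed in either or both genotypes, coloured by where they passed. Genes that passed in neither are not drawn. The genes called in both lie on the same side of 0 in both genotypes.

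At 0 Gy, Atm mice were compared with WT mice to see whether ATM deficiency alone changed blood transcripts. Of 24 B cell markers 22 had a higher mean (median 1.60), as had all 10 MHC class II genes (median 1.69), though no gene passed singly over all genes. Both lists were called with the preset correlation (adjusted p = 1.53e-16 and 2.3e-12) but not with an estimated one (adjusted p = 0.0591 for each), nor in the exact permutation test (p = 0.0844 and 0.0952). Cd79b was 3.26 higher (SE 1.39, adjusted p = 1), H2-Eb1 2.06 higher (SE 0.77, adjusted p = 1) and H2-Ab1 1.99 higher (SE 0.81, adjusted p = 1). When 1 array was left out these lay between 2.197 and 4.03, 1.19 and 2.65, and 1.199 and 2.57, lowest without WT 0 Gy replicate 6. Adjusted over the list alone, 8 of the 10 MHC class II genes passed. Heart muscle markers were lower (median -1.64, 6 genes, Myl3 -1.53, SE 0.75, -2.01 to -0.72 when 1 array was left out), but their shift was -0.63 and no longer called without WT 0 Gy replicate 3. Also called with the preset correlation were monocyte markers (0.49, adjusted p = 0.437 with an estimated correlation), mature neutrophil markers (0.31, adjusted p = 0.539 with an estimated correlation) and interferon-stimulated genes (0.45, adjusted p = 0.607 with an estimated correlation, and -0.08 on members detected on all arrays). So were inflammatory genes (0.28, adjusted p = 0.192 with an estimated correlation) and immediate early genes (0.29, adjusted p = 0.192 with an estimated correlation), and NK markers with a lower median (-0.43, adjusted p = 0.491 with an estimated correlation). The heart marker call had adjusted p = 0.192 with an estimated correlation. Without Atm 0 Gy replicate 1 the neutrophil median was -0.05 and the inflammatory call was lost (0.11). With limma 0 genes passed in all, 342 had an unadjusted p under 0.05 against 758 expected by chance, and 15 of all genes did not overlap between the groups. Within the days that held both genotypes (the first and the third) the B cell score differed by 1.29 and 2.91, that of MHC class II genes by 1.06 and 4.18, NK markers by -0.40 and -1.18 and monocyte markers by 0.17 and 1.26. Neutrophil markers differed by 0.20 and 0.33, interferon-stimulated genes by 0.40 and 0.37, inflammatory genes by 0.12 and 0.48, heart markers by -1.70 and -0.76 and immediate early genes by 0.37 and -0.25. On the 4 slides that held both genotypes, with 1 array of each, the B cell score differed by 0.496, -0.005, 3.98 and 2.91 and that of MHC class II genes by 0.84, -0.19, 3.60 and 4.18. NK markers differed by -0.305, 0.77, -1.23 and -1.18, neutrophil markers by 1.40, -0.55, -0.50 and 0.33, and heart markers by -0.69, 1.77, -6.23 and -0.76. The third of these slides held WT 0 Gy replicate 3, which had the lowest B cell score of the WT controls. With scan day and with slide as a block the medians of these lists, in the order given, were 1.64 and 1.82, 1.75 and 1.90, -0.68 and -0.56, and 0.42 and 0.44. For the later ones they were 0.19 and 0.12, 0.27 and 0.31, 0.28 and 0.21, -1.56 and -1.43, and 0.21 and 0.16. The neutrophil and immediate early calls were lost with slide as a block.

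At 0 Gy, Scid mice were compared with WT mice for the same purpose; Scid mice are known for their lack of mature B and T cells. Of 24 B cell markers 21 had a lower mean (median -1.40), of 28 T cell markers 24 (median -1.04) and of 10 MHC class II genes 9 (median -1.12). These lists were called with the preset correlation only, and no gene passed over all genes. Cd79b had a difference of -3.63 (SE 1.39, adjusted p = 0.899), H2-Ab1 had -1.61 (SE 0.81) and H2-Eb1 -0.64 (SE 0.77), the latter pair between -2.395 and -1.03 and between -1.51 and -0.051 when 1 array was left out. The T cell coreceptor genes Cd4 and Cd8b1 had -0.28 (SE 0.40, -0.62 to -0.048 when 1 array was left out) and 0.51 (SE 0.54, 0.11 to 0.73). Platelet genes were higher (all 29, median 0.66), as were NK markers (21 of 23, median 0.43) and globin genes (all 8, median 0.47). The calls had preset adjusted p = 3.43e-12 for B cell, 1.06e-10 for T cell, 4.02e-06 for MHC class II, 2.32e-08 for platelet, 0.00134 for NK and 0.0383 for globin genes. In the same order they had adjusted p = 0.241, 0.313, 0.378, 0.79, 0.79 and 0.79 with an estimated correlation. The exact permutation p of the scores was 0.149 for B cell and 0.108 for T cell markers. The library labelled WT 0 Gy replicate 3 had a B cell score of -2.40, against -1.71 to 1.64 in the other WT controls. The library labelled Scid 0 Gy replicate 4 had a score of 0.57, against -2.68 to -1.41 in the other Scid controls. Without this pair 35 genes passed, against 0 with all arrays (499 at an unadjusted p under 0.05, 758 expected) and 3 without WT 0 Gy replicate 3 alone. The pair was picked for scores that run against the difference between the genotypes. Its removal can raise the count for that reason alone, so the count decides nothing about the labels. Within the first and second scan day the scores differed by -1.59 and -1.75 for B cell, -0.84 and -1.94 for T cell, -1.50 and -2.07 for MHC class II, 0.94 and 0.31 for platelet, 0.37 and 0.71 for NK and 0.12 and 1.91 for globin genes. With scan day and with slide as a block the medians were -1.44 and -1.25, -1.27 and -1.21, -1.26 and -1.08, 0.61 and 0.50, 0.32 and 0.37, and 0.57 and 0.52. On the slide that held both libraries named above, the B cell score difference was 2.97, against -2.69, -4.03 and -2.20 on the other slides with both genotypes. T cell (1.91), MHC class II (2.55), platelet (-0.72), NK (-1.22) and globin scores (-1.27) on that slide also ran against their called direction. On the other slides with both genotypes they kept it. The globin call was lost without WT 0 Gy replicate 1, 2 or 5 or Scid 0 Gy replicate 1 or 5 (0.20 at the lowest). It was also lost in 8 of 21 other settings (adjusted p up to 0.699): normexp, quantile normalization, no filter, genes detected on all arrays, array weights, the dim or the liver-bright arrays left out, and brightness as a covariate.

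**Figure D4:**
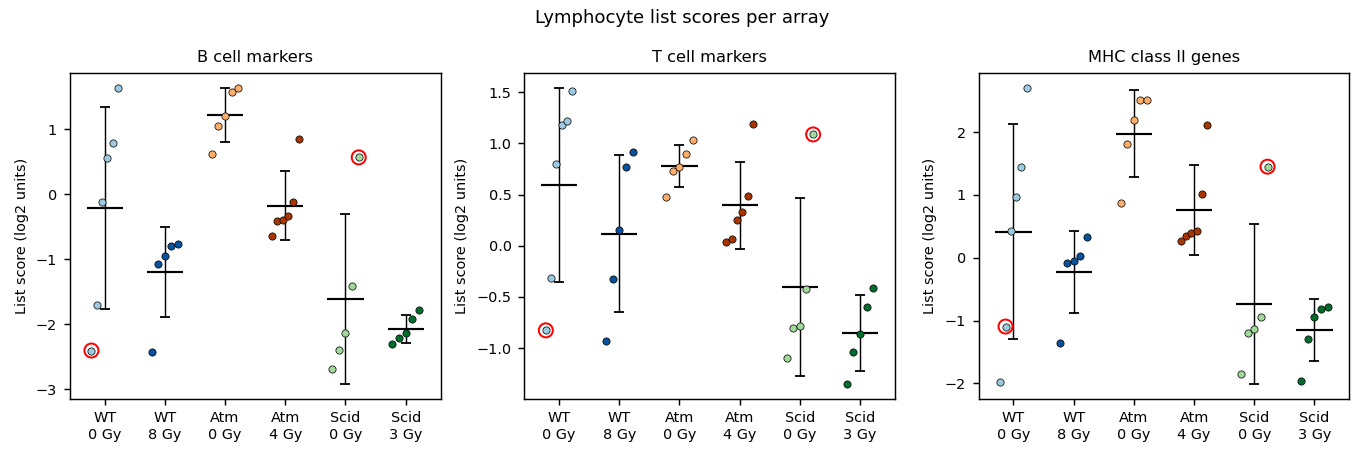
Mean log2 signal of the B cell, T cell and MHC class II lists, less the mean of all genes, in each of the 32 arrays by group, with lines at the group mean and bars of 1 SD. Red circles mark the libraries labelled WT 0 Gy replicate 3 (B cell score -2.40) and Scid 0 Gy replicate 4 (0.57).

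The responses to irradiation were then compared between genotypes, each at its own dose, to ask whether the deficient strains respond differently. Cdkn1a had an interaction of -2.66 (SE 0.73, adjusted p = 0.374) for Atm minus WT, -0.64 (SE 0.74, adjusted p = 0.765) for Scid minus WT and 2.01 (SE 0.74, adjusted p = 1) for Scid minus Atm. These values rest on its brightest probe. Its other kept probe rose by 1.86 in WT, 1.41 in Atm and 1.11 in Scid, which is a smaller gap between WT and Atm and the opposite order of Atm and Scid. With limma 0 genes passed in each of these comparisons, and 1296, 1080 and 639 genes had an unadjusted p under 0.05 against 758 expected. No single gene that passed in WT alone was thus shown to respond differently. For lists, 55 of 100 splits of the arrays reached the number called with the preset correlation for Atm minus WT. For Scid minus WT 27 did and for Scid minus Atm 90. A call with the preset correlation alone is thus weak evidence of a difference. By this preset test, erythroid genes as a group fell less in Atm than in WT (median of the interaction 1.45, adjusted p = 3.29e-18, adjusted p = 0.389 with an estimated correlation, and -1.33 with spike-in scaling). They also fell less in Scid than in WT (1.41, adjusted p = 7.47e-15, adjusted p = 0.361 with an estimated correlation). Adjusted over the list alone, 20 and 19 of the 37 passed, counts that do not allow for members moving together. The rise of p53 targets was smaller by the preset test in Atm (-0.71, adjusted p = 8.23e-05, adjusted p = 0.389 with an estimated correlation). That call was lost with normexp, with genes detected on all arrays and with brightness as a covariate (median -0.205 at the weakest, adjusted p up to 0.193). The rise was smaller too in Scid (-0.46, adjusted p = 0.000413, adjusted p = 0.361 with an estimated correlation), a call lost with genes detected on all arrays. That of interferon-stimulated genes was smaller in Atm as a group, 2 high arrays included (-1.20, adjusted p = 1.42e-05, adjusted p = 0.834 with an estimated correlation; 0.20 on members detected on all arrays) and in Scid (-1.06, adjusted p = 3.98e-07, adjusted p = 0.599 with an estimated correlation; 0.06 on these members). B cell markers fell further in Atm than in Scid (1 for Scid minus Atm, adjusted p = 4.77e-05, adjusted p = 0.886 with an estimated correlation). The mean B cell score at 0 Gy was 1.22 in Atm but -1.61 in Scid. Whether the lower start limited the fall in Scid was not tested. With scan day and with slide as a block these medians, in the order given, were 1.76 and 1.84, 1.44 and 1.43, -0.56 and -0.59, -0.33 and -0.25, -0.78 and -1.08, -0.77 and -0.73, and 1.09 and 1.22.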

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

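The tests of dim arrays and of lymphocytes in 1 Scid mouse were chosen only after the result they bear on was seen. So were those of scan day for both gene lists, and of brightness and liver RNA for the interferon-stimulated genes. The counts of splits were fixed before. The test of exchanged labels names libraries picked by their lymphocyte scores, so it was written after these scores were seen. Of the scalings tested, the detected-probe and spike-in ones were added after seeing the data.

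Of 282 values tested within groups for a single array far from the rest, 18 stood out, where chance alone gives about 1 in 20 groups, or 14. A gap to the nearest other array that took most of the group's range singled out each of these. They were the 75th percentile of the signal in WT 0 Gy replicate 5 (202.6, next 81.8), the B cell score (-2.42) and the MHC class II score (-1.36) of WT 8 Gy replicate 3, the proliferation score of WT 8 Gy replicate 2 (-2.00), the B cell score of Atm 4 Gy replicate 2 (0.85), the proliferation score (-0.81) and the interferon-stimulated score (-0.69) of Scid 0 Gy replicate 5, the globin score of Scid 3 Gy replicate 3 (8.14), the interferon-stimulated score of Scid 3 Gy replicate 2 (1.103) and the heart marker score of Scid 3 Gy replicate 4 (0.99). The library labelled Scid 0 Gy replicate 4 stood apart in its MHC class II score (1.45) and in Cd79b (5.41, next -2.25). Among single genes, Epb42 in Atm 0 Gy replicate 3 (3.30, next 2.53) and Slc19a2 in WT 0 Gy replicate 5 (0.84, next -2.18) also did. So did Slpi in WT 0 Gy replicate 2 (7.88, next 6.58), Sod2 in WT 0 Gy replicate 4 (3.00, next 5.81), and Camp (-0.32, next 0.97) and Fcer2a (-4.61, next -3.07) in WT 8 Gy replicate 1.

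A test of the difference between genotypes in the response to irradiation singled out 17 list medians with the preset correlation. For Atm minus WT these were p53 targets (-0.71), NK markers (0.49; -0.02 with normexp, -0.04 with the array median), monocyte markers (-0.87), erythroid genes (1.45), globin genes (1.24; -0.21 with normexp), proliferation genes (0.26; -0.27 with the array median, -0.20 with the authors' values) and interferon-stimulated genes (-1.20). For Scid minus WT they were p53 targets (-0.46), B cell markers (0.54; -0.02 with the array median), monocyte markers (-0.75), mature neutrophil markers (-0.47), erythroid genes (1.41), globin genes (1.12), interferon-stimulated genes (-1.06) and immediate early genes (-0.69). For Scid minus Atm they were B cell markers (1) and NK markers (-0.69). None of the 17 was called with an estimated correlation, whose adjusted p was 0.884 for NK and monocyte markers, 0.43 for globin and 0.809 for proliferation genes in Atm minus WT, 0.657 for B cell, monocyte and neutrophil markers, 0.599 for globin and 0.361 for immediate early genes in Scid minus WT, and 0.886 for NK markers in Scid minus Atm. Without 1 array the calls of NK markers (Atm minus WT, 7 arrays, 0.19 at the lowest), monocyte markers (Atm minus WT without WT 8 Gy replicate 1, -0.60), and B cell (7 arrays, 0.17), monocyte (6 arrays, -0.41) and neutrophil markers (5 arrays, -0.30) in Scid minus WT were lost.

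The library labelled Scid 0 Gy replicate 4 lay above all other Scid controls in its B cell, T cell and MHC class II scores. That labelled WT 0 Gy replicate 3 lay below the other WT controls in its B cell score (-2.40, lowest other -1.71) and T cell score (-0.83, lowest other -0.32). Its MHC class II score (-1.095) lay within their range (-1.985 to 2.70). A score of 232 genes outside the lymphocyte lists, chosen in irradiated arrays alone, placed WT 0 Gy replicate 3 at 0.36 and Scid 0 Gy replicate 4 at -1.29, a difference of 1.64, against means of -0.63 in the other WT and 0.58 in the other Scid controls. Exchanged labels are a candidate explanation with these values. In this score, however, the WT library lies inside the range of the other WT controls (-2.12 to 0.86). The 232 genes may still hold lymphocyte transcripts, and no probe of a targeted gene can decide. The WT library also had the highest heart muscle score of all arrays (3.76, against at most 1.66 in the other groups). Whether this bears on its other scores was not tested. From its slope in the other 0 Gy arrays of WT and Scid, brightness predicted 16.2% of the B cell score deviation of WT 0 Gy replicate 3. For Scid 0 Gy replicate 4 it predicted 26.2%. These shares are small, but no error of the slope was computed, so dim arrays are not excluded. Lymphocytes in 1 Scid mouse, which would leave the WT library in place, could not be excluded, since its B cell score lay below the lowest other WT control by -0.69, within their SD of 1.25.

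Erythroid and reticulocyte genes fell in irradiated WT mice. The list passed the exact permutation test of its score but not the test with an estimated correlation. Scaling to the 75th percentile is argued against as the whole cause, since the median of the list was -2.55, -2.11, -2.46 and -1.61 under the array median, quantile, detected-probe and spike-in scalings. Scaled to spike-in probes, the list differed by -1.14 (SE 0.25, exact permutation p = 0.00649) while all genes differed by 1.17. Scan day is argued against as well, since the list score differed by -2.00 within the second day (3 irradiated arrays and 2 controls); the first day held 1 irradiated array and is not counted. A fall of erythroid transcripts with irradiation, which may come from fewer reticulocytes or less transcript in each, stays open as a hypothesis, and neither was measured.

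Interferon-stimulated genes rose in irradiated WT mice, against 0.08 in Atm and 0.15 in Scid as list medians, although 2 of 6 irradiated Atm arrays (1.897 and 1.503) scored above every irradiated WT array. The list's call was lost with an estimated correlation, in WT and in both interactions with WT. Its median in WT was -0.57 with only the members detected on all arrays. Scan day is argued against, with a rise of 0.82 (SD of the WT controls 0.21) within the second day (3 irradiated arrays and 2 controls). Of these, WT 8 Gy replicate 2 and WT 0 Gy replicate 5 were bright in liver genes. The first day held 1 irradiated array, also bright in liver genes, and is not counted. Array brightness, which was higher at 8 Gy by 11.48 percentage points, predicted 16.4% of the difference from its slope within the 0 Gy groups (0.18, SE 0.14). Liver RNA on WT 8 Gy arrays is argued against, since the score still differed by 1.03 without the 4 arrays bright in liver genes. A response to the irradiation may stand behind the rise, as a hypothesis found and tested on the same data, in which dose cannot be told from genotype.

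For each comparison, 100 splits of the same arrays into groups of the same sizes were fitted, the real one included. Only the real split, 1 of 100, reached the 1092 genes called in WT. The highest other was 851, in a split that differs from the mirror of the real one by 1 array. The same held for the 36 in Atm (highest other 3) and the 163 in Scid (highest other 106). Chance is argued against for these counts on all arrays, but 100 splits resolve no share under 1 in 100. The counts were not stable: they were 2 without Atm 0 Gy replicate 2 and 43 without Scid 0 Gy replicate 2. No splits were made of the arrays left in these cases. The splits take no account of scan day, which nearly coincides with dose in Atm. With scan day as a block 820 genes passed in WT (789 of the 1092), 0 in Atm and 69 in Scid (68 of the 163), so scan day is not excluded for the 36 genes of Atm. These kept their direction on the first day (36 of 36, 1 irradiated array) and on the third (34 of 36, 1 array of each group), which their selection on the same arrays partly fixes. With the block their median size was 1.55, against 2.05 without it. Where 0 genes were called every split reaches the count, 100 of 100, so the splits decide nothing. This holds for Atm against WT (highest other 2), Scid against WT (highest other 1154), and the interactions Atm minus WT (highest other 1668), Scid minus WT (highest other 5830) and Scid minus Atm (highest other 3996). Splits that call over 1000 genes may point to a structure of the samples, which was not tested. Chance cannot be excluded for the number of lists called with the preset correlation: 42 splits reached the 9 lists of WT (highest other 17), 26 the 7 of Atm (11), 49 the 6 of Scid (11), 23 the 9 of Atm against WT (12), 47 the 6 of Scid against WT (12), 55 the 7 of Atm minus WT (13), 27 the 8 of Scid minus WT (11) and 90 the 2 of Scid minus Atm (13).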

How the results depend on the processing

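The settings chosen after seeing the data were scaling to the 75th percentile of probes detected on all arrays, spike-in scaling, genes detected in a group compared, leaving out 3 dim, 4 liver-bright or 2 unlike arrays, brightness as a covariate, the exact permutation test of list scores, and for the shared genes a fit of each genotype on its own 2 groups. Over the settings other than leaving out 1 array, log2 fold changes of named genes stayed on their side of the threshold without a reversal in 5581 cases. They lost a call in 441, gained one in 71 and reversed in 19. A change of sign counted as a reversal only where the gene passed in the main fit or in the setting. The 5581 may thus hold changes of sign in genes that passed in neither. List medians kept direction and call in 1016 cases, lost a call in 78 and reversed in 28. The p53 list in WT (0.23 to 2.35), erythroid genes in WT (-3.03 to -1.04), Atm (-2.67 to -0.57) and Scid (-1.59 to -0.49) and B cell markers in Atm (-3.06 to -0.84) stayed called in every setting that kept the preset list test. In Atm this is weak support, since 26 of 100 splits of its arrays reached the 7 lists called by that test. The erythroid score in Atm differed by -0.15 within the first and -0.15 within the third scan day, against -0.86 over all its arrays. The cause of the changes was not tested unless stated. The genes called in WT (1092) became 591 with normexp, 672 with the array median, 539 with slide as a fixed block, 3059 with array weights, 4213 with spike-in scaling and 552 with brightness as a covariate. In Atm, 36 genes became 1 with normexp, 184 with the array median and 7 without the filter on dim probes. There were 110 with only the 5163 genes detected on all arrays, where fewer genes are tested. Blocks gave 0 genes in Atm with slide, 8 with slide series, 0 with scan day and 75 with the replicate number as a block, although the numbers do not pair the arrays (r from -0.73 to 0.45 between arrays of the same number). Fitting only the 2 groups compared gave 0, where fewer arrays estimate the spread. Array weights gave 550, the authors' values 339, the detected-probe percentile 108, spike-in scaling 10782 and brightness as a covariate 268. Leaving out the 3 dim arrays gave 213 and the 4 liver-bright arrays 11. In Scid, 163 genes became 0 with normexp, 54 without the filter, 247 with genes detected on all arrays, 85 with slide and 69 with scan day as a block. There were 31 with only the 2 groups, 1237 with array weights, 368 with the authors' values, 0 with spike-in scaling, 557 without the dim arrays, 267 without the liver-bright arrays and 258 with the covariate. In the 0 Gy comparisons, 0 genes became 1 in Atm against WT with only the 2 groups. In Scid against WT they became 23 with array weights and 35 without the 2 unlike arrays. For the interactions, 0 genes became 36 with slide as a block and 13654 with spike-in scaling (Atm minus WT). They became 22 with array weights and 2 without the 2 unlike arrays (Scid minus WT), and 5441 with spike-in scaling (Scid minus Atm). The median log2 fold change of all genes was -0.024 in WT, -0.155 in Atm and 0.009 in Scid in the main analysis. With spike-in scaling it was 1.25, -1.66 and 0.30, and the counts and reversals of that setting go with this. In Atm the log2 spike-in signal ran from 12.84 to 14.57 at 4 Gy, against 11.84 to 13.14 at 0 Gy. The 75th percentile of the signal ran from 17.7 to 111.5 and from 28.1 to 95.7. The shift in Atm thus goes with a higher spike-in signal and need not come from blood transcripts. The median of all genes was 0.32, -0.345 and -0.21 with the array median, 0.41, 0.098 and 0.199 with the detected-probe percentile, and 0.37, -0.26 and -0.148 with the authors' values. With quantile normalization it was 0.13 in WT and -0.165 in Atm. Of the lists, 9 in WT became 1 with an estimated correlation and 5 with the exact permutation test. In Atm 7 became 3 with genes detected on all arrays, 0 with an estimated correlation, 2 with fry and 0 with the exact test. In Scid 6 became 14 without the filter, 10 with spike-in scaling, 0 with an estimated correlation, 0 with fry and 0 with the exact test. At 0 Gy, 9 lists in Atm against WT became 3 with genes detected on all arrays, and 6 in Scid against WT became 2. Both became 0 with an estimated correlation, 0 with fry and 0 with the exact test. In Atm minus WT, 7 lists became 4 with the covariate, and in Scid minus WT 8 became 5 with the authors' values. In Scid minus Atm, 2 became 5 with normexp, 4 with quantile normalization, 5 without the filter, 0 with genes detected on all arrays, 5 with slide and 6 with scan day as a block. They became 8 with array weights, 4 with the authors' values, 4 with the detected-probe percentile, 6 with spike-in scaling and 4 without the unlike arrays. All interactions had 0 lists with an estimated correlation and 0 with fry. The 145 genes shared between genotypes became 0 with normexp, 245 with the array median, 50 without the filter, 230 with genes detected on all arrays, 79 with slide and 62 with scan day as a block. They became 902 with array weights, 353 with the authors' values, 372 without the dim arrays, 223 without the liver-bright arrays, 226 with the covariate, 33 at an adjusted p under 0.01 and 30 with each genotype fitted on its own 2 groups.

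Leaving out 1 array at a time gave 688 (WT 8 Gy replicate 1) to 1835 genes (WT 0 Gy replicate 5) in WT. It gave 2 (Atm 0 Gy replicate 2) to 274 (Atm 4 Gy replicate 1) in Atm and 43 (Scid 0 Gy replicate 2) to 403 (Scid 0 Gy replicate 5) in Scid. The 0 Gy comparisons had 0 to 0 genes (Atm) and 0 to 3 (Scid, 3 without WT 0 Gy replicate 3). The interactions had 0 to 3 (Atm minus WT, 3 without WT 0 Gy replicate 5), 0 to 1 (Scid minus WT, 1 without Scid 0 Gy replicate 1 or WT 0 Gy replicate 3 or 5) and 0 to 0 (Scid minus Atm). Lists called ran from 8 to 11 in WT, 6 to 9 in Atm, 6 to 8 in Scid, 8 to 12 in Atm against WT and 5 to 9 in Scid against WT. For the interactions they ran from 6 to 8, 5 to 12 (12 without Scid 0 Gy replicate 2) and 2 to 7. The shared genes ran from 52 to 319.

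Other calls of lists were lost in these settings, beside the reversals below and the losses given elsewhere. In WT these were B cell markers without the filter, globin genes with quantile normalization and the covariate, and ribosomal protein genes without the filter and with genes detected on all arrays. In Atm they were p53 targets without the filter and with genes detected on all arrays, the platelet list with normexp and without the filter, MHC class II genes with spike-in scaling, and ribosomal protein genes with quantile normalization and with genes detected on all arrays. In Scid they were p53 targets and NK markers with genes detected on all arrays, the platelet list with array weights and ribosomal protein genes with normexp. In Atm against WT they were NK markers with genes detected on all arrays, inflammatory genes with array weights and immediate early genes with normexp. In Scid against WT they were T cell and NK markers with genes detected on all arrays. For Atm minus WT they were erythroid genes with normexp, monocyte markers in 8 settings, NK markers in 5, globin genes in 3 and proliferation genes without the filter. For Scid minus WT they were B cell markers in 3, monocyte markers in 6, globin genes in 3 and immediate early genes in 2, and neutrophil markers with the authors' values. For Scid minus Atm they were B cell markers with spike-in scaling and NK markers with genes detected on all arrays.

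Reversals followed the scaling in most cases. With spike-in scaling the median turned from -0.91 to 0.37 for B cell markers, from -1.26 to 0.13 for globin genes, from -0.45 to 0.82 for proliferation genes and from -0.61 to 0.67 for ribosomal protein genes in WT. In Atm it turned from 0.41 to -1.09 for p53 targets and from 0.06 to -1.44 for the platelet list. For Atm minus WT it turned to -2.29 for NK markers, -1.33 for erythroid, -1.55 for globin and -2.52 for proliferation genes. For Scid minus WT it turned to -0.45 for B cell markers, and for Scid minus Atm to 1.1 for NK markers. Single genes also turned with it: Ms4a4c (-1.16 to 0.12), Rplp2 (-1.22 to 0.061) and Rpl28 (-1.18 to 0.10) in WT, and S100a8 (0.02 to -1.48) and Pf4 (0.01 to -1.49) in Atm. For Atm minus WT these were Abhd4 (0.43 to -2.36), Ccl5 (0.04 to -2.74), Csf1r (0.32 to -2.47), Alas2 (1.15 to -1.64), Hba-a1 (1.60 to -1.18), Hba-a2 (1.197 to -1.58), Cd3e (0.65 to -2.13) and Pf4 (0.20 to -2.58). With normexp, globin genes turned to 0.13 and ribosomal protein genes to 0.67 in WT. So did NK markers (-0.017) and globin genes (-0.21) for Atm minus WT, and Ms4a4c (0.13), Rps14 (-1.35 to 0.012), Rplp2 (0.059), Rpl28 (0.12) and Dclre1c (1.12 to -0.047) in WT. With quantile normalization ribosomal protein genes (0.073) and Gng11 (-0.13 to 1.05) turned in WT. With the array median the platelet list turned in Atm (-0.13), NK markers (-0.038) and proliferation genes (-0.27) for Atm minus WT and B cell markers (-0.017) for Scid minus WT. The authors' values turned the platelet list in Atm (-0.077) and proliferation genes for Atm minus WT (-0.20), and the covariate the platelet list in Atm (-0.074). With genes detected on all arrays, interferon-stimulated genes turned in WT (-0.57), in Atm against WT at 0 Gy (-0.083), for Atm minus WT (0.20) and for Scid minus WT (0.063), since only the bright members stay in the list. The platelet list in Atm turned without Atm 4 Gy replicate 1 (-0.18), Atm 0 Gy replicate 4 (-0.01) or Atm 4 Gy replicate 4 (-0.20), with -0.20 to 0.39 over all omissions. Mature neutrophil markers in Atm against WT at 0 Gy turned without Atm 0 Gy replicate 1 (-0.053 to 0.60 over all omissions). Dim arrays limit what can be seen, since a gene near background has compressed or unstable values, and between 20.02 and 58.63% of probes were well above it.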

Other observations

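The test of erythroid transcripts among the interferon-stimulated members that fell was chosen only after the result was seen, as was the list of liver genes.

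Several gene groups showed no shift in irradiated WT mice with the preset correlation, and single members still moved. Of the NRF2 and antioxidant list 5 of 22 genes fell and none rose, with a median of 0.27 but a mean of -0.14 (adjusted p = 0.501). These were, chosen after their values were seen, the glutathione peroxidase gene Gpx1 (-2.89), the glutamate-cysteine ligase modifier gene Gclm (-2.02), the superoxide dismutase gene Sod2 (-1.70), Nqo1 (-1.69) and the catalase gene Cat (-1.66). When 1 array at a time was left out, the call of Sod2 was lost in 6 of 11 cases (-1.49 at the weakest), that of Nqo1 in 2 (-1.48) and that of Cat in 3 (-1.38). In Scid mice Gpx1 fell too (-2.20). Among 15 genes of non-homologous end joining, Dclre1c, which encodes Artemis, rose (1.12, and 0.66 on its other probe, but -0.047 with normexp background correction, and not called in 8 of the 11 omissions, 0.92 at the lowest; chosen after its value was seen), and the list's median was -0.12 (adjusted p = 0.525). The 6 homologous recombination genes had a median of -0.08 (adjusted p = 0.946).

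Among cell type markers in irradiated WT mice, T cell markers had a median of -0.39 (adjusted p = 0.114), NK markers -0.45 (adjusted p = 0.28), MHC class II genes -0.52 (adjusted p = 0.159), dendritic cell markers -0.32 (adjusted p = 0.257, but fry adjusted p = 0.0115) and eosinophil markers -0.38 (adjusted p = 0.422). Of the T cell list, Cd8a fell (-2.59) and of the MHC class II list its transactivator gene Ciita fell (-1.58), both chosen after their values were seen. Mature neutrophil markers had a median of -0.17 and a mean of 0.05 (adjusted p = 0.386): Padi4 (2.14, and 1.17 on its other probe) and Slpi (1.73) rose and Mxd1 fell (-1.72, but -0.36 on its other probe). Neutrophil granule genes had a median of -0.05 and a mean of 0.16 (adjusted p = 0.432): Tcn2 rose (1.79) and Camp fell (-1.40). These 5 genes were also chosen after their values were seen. Over the 11 omissions the calls were lost in 3 for Ciita (-1.325 at the weakest), 4 for Padi4 (1.79), 1 for Mxd1 (-1.50), 6 for Tcn2 (1.47) and 8 for Camp (-1.105). Basophil markers had a median of 0.58 (adjusted p = 0.159, exact permutation adjusted p = 0.0497), immediate early genes 0.58 (adjusted p = 0.244), inflammatory and NF-kB genes -0.26 with a mean of 0.04 (adjusted p = 0.919) and heart muscle markers -0.72 (adjusted p = 0.489).

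The 3 interferon-stimulated members that fell in WT, Rsad2 (-3.84), Isg15 (-2.33) and Oas3 (-2.62), were not called in Atm (-1.84, -0.62 and -1.70) or in Scid (-1.88, -0.90 and -1.77). Over the 16 arrays at 0 Gy, with group means removed, their mean followed the erythroid score (Pearson r = 0.924, permutation p = 1e-05, the smallest possible, adjusted p = 2e-05; Spearman rho = 0.926, p = 2e-05) and did so without the 2 arrays farthest out (r = 0.868) and within the first scan day (r = 0.875, 11 arrays). With the score of the other members of their own list r was 0.351 (permutation p = 0.181, adjusted p = 0.181; rho 0.288, p = 0.28), and these 2 relations were the ones computed. Transcripts of erythroid cells may therefore account for their signal at 0 Gy and, with the fall of erythroid genes, for their fall, which is a hypothesis from the same data.

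Liver genes, such as the albumin gene Alb, the fibrinogen gene Fgb and the antithrombin gene Serpinc1, were bright on 4 arrays: WT 0 Gy replicate 5, WT 8 Gy replicates 1 and 2 and Atm 4 Gy replicate 3. Of 30 listed genes 22 were tested, none of them in another list. The mean of these genes less that of all genes was 6.37 to 6.99 on these arrays and -2.89 to 3.69 on the other 28, and the widest gap between ordered arrays was 2.68. Alb had a mean of 9.55 ± 0.40 (SD, n = 4) on these arrays and -0.53 ± 3.09 (SD, n = 28) on the others. The list's median was 1.495 in irradiated WT and 1.72 in irradiated Atm mice, with 0 members called by limma and exact permutation p = 0.548 and 0.418 for the score. The labels state that blood was drawn by cardiac puncture, and where these transcripts came from was not tested.

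The correlation of the log2 signal between arrays ran from 0.617 to 0.983, and 0 pairs of arrays were identical. The first 3 principal components held 36.1, 13.3 and 9.5% of the variance.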
